A study of Drosophila melanogaster with 70 samples.

How the data were processed

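In situ Hi-C, which ligates and sequences pairs of DNA ends that lie close together in the nucleus, was measured in Drosophila melanogaster embryos staged by hand. The enzyme DpnII cut the chromatin, and libraries were read as paired ends of 75 bp, per the labels' protocols. At stage 5 (nuclear cycle 14, the blastoderm) there were 3 libraries from mothers with a control RNAi and 2 from mothers with RNAi against mof. At stage 15 (14 to 16 h after egg laying) there were 8 libraries, 2 for each combination of sex and RNAi. The stage 5 libraries did not come from sexed embryos. The other 57 of the 70 samples of the series (ATAC-seq, ChIP-seq of H4K16ac, H3 and RNA polymerase II, and inputs) were not analysed here. The strain labels of the mof RNAi Hi-C samples speak of control RNAi mothers but give the mof RNAi stock, so the groups follow the titles.

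The authors deposited lists of domain boundaries called on bins of 2.5 kb of the dm6 assembly, per the labels and file names. Each boundary has a score that is the authors' own deposited value on a scale that is not stated, running from negative to positive. It was used only within 1 list, by its rank, sign and medians, and never compared between lists. No table here tests whether a more negative score means a stronger boundary. The aligner, the boundary caller, its version, thresholds and filters are not given in the sources used here. Each list was taken to pool libraries: 1 list for stage 5 control, 1 for stage 5 mof RNAi, and 1 for stage 15. The stage 5 lists were tied to their groups by the stage and condition in the file names. The descriptions of all 8 stage 15 libraries name that last list, and which of them were pooled is not stated. Another list for stage 5, named in the sample descriptions, was identical to the control list byte for byte and was not used. No list gives read counts, so the depth is unknown. With 1 pooled list per condition there is no spread between replicates, and no p-value was computed.

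A boundary was placed at the midpoint of its interval, and 2 boundaries were matched when their midpoints lay within 2.5 kb. A domain is the stretch between neighbouring boundaries of 1 list on an arm. Shares have 95% Wilson intervals, which treat boundaries as independent and cover counting error only. Each share was set beside 1000 rotations of the query list, with every arm rotated by its own random offset, and percentiles among rotations are descriptions of these lists. X and autosomes were compared by 10000 rotations of the matched status along the order of boundaries. Median scores of unmatched boundaries were set beside 10000 random sets of the same size from the same list. Intervals of differences come from 2000 bootstrap draws over boundaries.

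The numbers in the boundary names count bins. Where fewer numbers than bins separated neighbouring boundaries, the missing bins were taken as left out of that map by the authors. Why they were left out is not given in the sources used here. A list numbered over all bins would show none missing, whether or not bins were left out.

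Genes came from a table of the release 6 assembly that matches dm6, with 13842 protein-coding genes on the 5 arms. It holds no strand, so the planned distance to transcription start sites was replaced by the distance to either annotated end of a gene. A gene was at a boundary when an end lay within 2.5 kb of the boundary's midpoint. Planned counts of sequence motifs were not run, because no genome sequence was used here. The lists hold boundaries on 2L, 2R, 3L, 3R and X only, so genes of chromosome 4 (pho and bt among the listed genes) were left out.

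The 12 gene lists, the planned comparisons and the rule for named genes were fixed before the data were examined. Named are the 10 boundaries of each list without a partner within 10 kb in the other that have the most negative scores, each with its nearest gene. Also named are up to 4 genes per gene list within 5 kb of such a boundary, nearest first, and 14 loci whatever their values (eve, ftz, Ubx, abd-A, Abd-B, Antp, en, Kr, sna, mof, msl-3, roX1, roX2 and Sxl). Other members of the gene lists are named where a list's count is spelled out, and these were chosen after their values were seen. To ask whether genes of a list at a boundary in 1 list were also at a boundary in another, their count was set beside 10000 random sets of the same number of protein-coding genes at boundaries of the first list. The random sets hold no noncoding genes, so the comparison is not read for the MSL list, which holds roX1 and roX2. This comparison, the set that joins segmentation and early zygotic genes, and 2000 sets matched on score decile were added after the data were examined.

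Alternatives were matching tolerances of 0, 5 and 10 kb, one-to-one matching, the 50% of each list with the most negative scores, domains without the shortest or longest ones, other windows around gene ends and gene ends of every biotype. X was also set against each autosomal arm alone. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Matching was tested on simulated data. A rotated control list of 2591 boundaries matched another rotation of it at 13.6%, against a mean of 13.9% over further rotations. Copies that kept 79.0%, 76.4% and 50.0% of the control list came back as 79.7%, 77.6% and 53.3% matched. Kept boundaries were shifted by at most 1 bin, so all of them matched by construction, and larger shifts were not simulated. In the second copy an X minus autosome difference of -20.7 points came back as -18.0.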

Results

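MOF is the acetyltransferase that places acetyl groups on lysine 16 of histone H4. It acts in the MSL complex, which serves dosage compensation on the male X, and in the NSL complex. The Hi-C part of the series set embryos of mothers depleted of mof beside control embryos at stage 5, and stage 5 beside stage 15. Domain boundaries were read from 3 lists, each taken to pool the libraries of its group. They held 2591 boundaries at stage 5 in control embryos (3 libraries), 2499 at stage 5 after maternal mof RNAi (2 libraries) and 2785 at stage 15 (8 libraries named). Depth is unknown, and 1 pooled list per condition leaves no replicate check of any difference.

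The pair-rule gene eve lay in a domain of 17.5 kb with the same ends in all 3 lists, between boundaries at 2R 9971251 to 9973750 and 9988751 to 9991250. The pair-rule gene ftz lay in a domain of 65 kb that was also the same in all 3, on 3R from the boundary at 6846251 to that at 6911251. The median domain was 38.6 kb at stage 5 in control (95% bootstrap interval 37.5 to 40, quartiles 25 and 62.5 kb). It was 40 kb after mof RNAi (40 to 42.5, quartiles 25 and 65 kb) and 35 kb at stage 15 (35 to 35, quartiles 22.5 and 57.5 kb). On X the medians were 40, 40 and 35 kb. The stage 5 maps left out 9.10% of the spanned bins in control and 9.09% after mof RNAi. The numbers in the stage 15 list showed 0 missing of 52388. None of its boundaries was wider than 2.5 kb, while 140 in each stage 5 list were. Whether bins were left out of the stage 15 map is therefore not known.

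The first comparison asked which stage 5 boundaries were also called after maternal depletion of mof. All 9 segmentation genes at a control boundary were at one after mof RNAi: the gap genes hb, Kr, kni and tll, the pair-rule genes hry and run, and en, inv and hh. The 6 early zygotic genes at a control boundary were at one in both lists as well: sisA, bnk, Sry-alpha, term, slam and the sex determination switch Sxl. Of 59 ribosomal protein genes at a control boundary, 55 were at a mof RNAi boundary (93.2%, 83.8 to 97.3), beside 83.9% of all 4368 protein-coding genes at control boundaries. Across the genome, 2039 of 2591 control boundaries had a partner after mof RNAi (78.7%, 77.1 to 80.2), against a mean of 13.4% over rotations. In the other direction it was 2039 of 2499 (81.6%, 80.0 to 83.1), so 552 boundaries were called in control only and 460 after mof RNAi only.

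Genes of the MSL complex and its partners divided. mle and Clamp were at boundaries in both stage 5 lists, msl-1 in control only, and mof itself had its nearest boundary 3.15 kb away in all 3 lists. At roX1, 1 of the 2 noncoding RNAs of the complex, a boundary lay inside the gene in both lists, starting at X 3861251 in control and at 3858751 after mof RNAi, which is 1 bin. At roX2, the other RNA, the nearest boundary was 9.07 kb from the gene in control and 0.432 kb from a gene end after mof RNAi and at stage 15. The genes nsl1, dgt1, Rcd5, MBD-R2 and wds of the NSL complex were at boundaries in both stage 5 lists. For none of the 11 gene lists made of protein-coding genes did the count shared between the stage 5 lists lie outside the central 95% of random gene sets. From control, the muscle list (1 gene, range 0 to 1) and the epidermis, gut and trachea list (2 genes, range 0 to 2) could not. In either direction, only the ribosomal protein list of these 11 could lie above its range, since the others' ranges reached their full count. From control, 79.8% of random sets kept fewer than the 9 segmentation genes, and 65.3% fewer than the 6 early zygotic genes. For the MSL list the shared count was 2 of 4, roX1 among the 4, without a comparison to random sets.

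The control list had boundaries without a partner within 10 kb after mof RNAi at msl-1 (2L 18681251 to 18683750, nearest 17.5 kb away) and at the insulator gene su(Hw) (3R 14306251 to 14308750, 20 kb). Others lay at the mesoderm gene sna (2L 15476251 to 15478750, 22.5 kb), at the chromatin remodeller brm (27.5 kb), and at RpL27 (22.5 kb) and RpL10 (30 kb). RpS10a had such a boundary 2.76 kb from its end. In all, 444 control boundaries (17.1%) had no partner within 10 kb. The 10 with the most negative scores lay nearest to Mnn1, Diap2, CG9300, CG8814, Vps8, Rsph3, TfIIS, Flacc, fz4 and dlg1. After mof RNAi, 353 boundaries (14.1%) had none within 10 kb in control. The 10 most negative of those lay nearest to sgl, DPCoAC, CG13455, Qsox1, CG3662, His3.3B, CG34298, Msp300, mei-W68 and Cnx99A, and 1 lay 3.54 kb from RpL38. Of 2586 control domains, 1509 (58.4%, 56.4 to 60.2) had both ends and nothing between them after mof RNAi, 139 gained a boundary inside, and 938 lacked at least 1 end.

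On X, 352 of 463 control boundaries were called after mof RNAi (76.0%, 71.9 to 79.7), beside 79.3% on the autosomes (77.5 to 80.9). The arms 2L, 2R, 3L and 3R stood at 79.6%, 80.6%, 76.7% and 80.3%. The difference of X minus autosomes was -3.25 percentage points (95% bootstrap interval -7.55 to 0.874) and lay at the 15.2th percentile of the rotations, inside their central 95%. From the mof RNAi list it was -4.32 points (-8.39 to -0.465), at the 3.39th percentile of rotations. A lower share on X was not separable from the arrangement of unmatched boundaries along the genome.

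**Figure D1:**
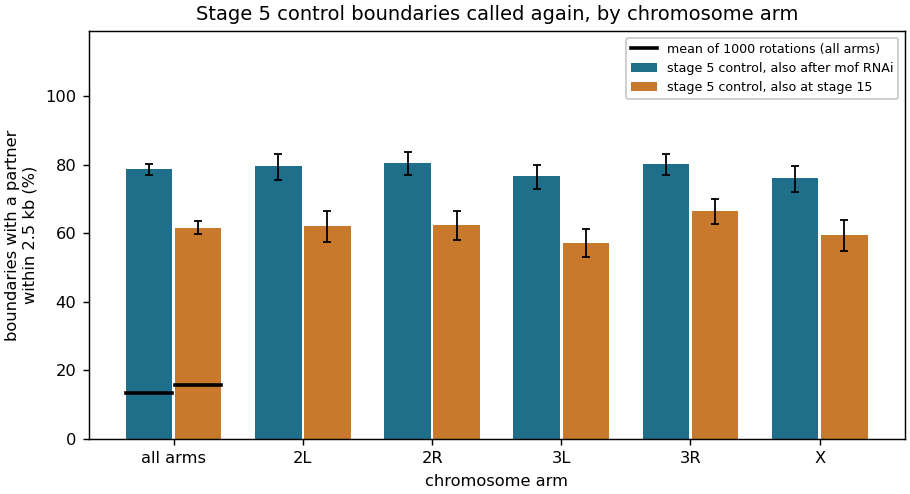
Share of stage 5 control boundaries (%) with a partner within 2.5 kb after mof RNAi (blue) and at stage 15 (orange), for all arms and each arm. Error bars are 95% Wilson intervals and black lines the means over 1000 rotations; the share after mof RNAi runs from 76.0% on X to 80.6% on 2R.

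Boundaries that were called again had more negative scores within their own list. The median score of control boundaries without a partner after mof RNAi was -0.0118, beside -0.370 for those with 1, and 0 of 10000 random sets reached a median as high. In the control decile with the most negative scores, 97.3% (94.5 to 98.7) had a partner after mof RNAi, and in the least negative decile 49.0% (43.0 to 55.1). Of the 1994 control boundaries with negative scores 85.8% had a partner, and of the 597 with positive scores 55.1%. Boundaries absent after mof RNAi at sna (-0.324), msl-1 (-0.397), su(Hw) (-0.407) and RpL27 (-0.532) scored below the list's median of -0.304. Those at brm (-0.219) and RpL10 (0.00749) and near RpS10a (-0.0559) scored above it.

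**Figure D2:**
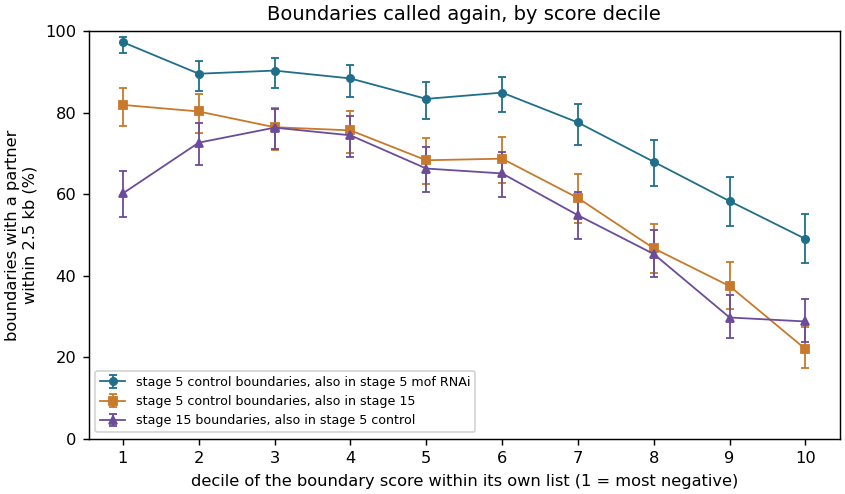
Share of boundaries (%) with a partner within 2.5 kb by decile of the authors' score within the boundary's own list, from the most negative (1) to the least (10), with 95% Wilson intervals. From decile 1 to 10 the share falls from 97.3% to 49.0% for control boundaries after mof RNAi, while for stage 15 boundaries decile 1 stands at 60.2%, below decile 3 at 76.3%.

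The second comparison set stage 5 beside stage 15, when organs have formed. Of the 9 segmentation genes at a stage 5 control boundary, en and hh were at a stage 15 boundary, while hb, Kr, kni, tll, hry, run and inv were not. Of the 6 early zygotic genes, Sxl was at a stage 15 boundary, and sisA, bnk, Sry-alpha, term and slam, which act around cellularization and early sex determination, were not. Of all protein-coding genes at a stage 5 boundary, 75.5% were at a stage 15 boundary, and 48 of 59 ribosomal protein genes were (81.4%, 69.6 to 89.3). Only 0.15% of random gene sets kept as few as the 2 of 9 segmentation genes, and 0.37% as few as the 1 of 6 early zygotic genes. The counts of the other 9 lists of protein-coding genes lay inside the central 95% of random sets. The muscle list, with 1 gene and a range of 0 to 1, could not lie outside. Nor could the epidermis, gut and trachea list, which kept 0 of 2 with a range of 0 to 2. Of these 9 lists, only the ribosomal protein list could lie above its range, since the others' ranges reached their full count. With windows of 1 kb around gene ends, segmentation genes stood at 1 of 3 and early zygotic genes at 1 of 4. There 20.1% and 7.78% of random sets kept as few. With windows of 5 kb segmentation genes stood at 4 of 10 (0.79%). The early zygotic count no longer lay outside the central 95% with windows of 5 kb (3 of 7, 3.70%), stage 15 boundaries within 10 kb (3 of 6, 3.00%) or genes without left-out bins (1 of 3, 13.7%).

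The boundary at Kr (2R 25226251 to 25228750) had a positive score (0.352) and was 45 kb from the nearest stage 15 boundary, that at inv (2R 11473751 to 11476250) 22.5 kb, and those at kni and hb 15 kb each. At Sry-alpha the boundary at 3R 30038751 to 30041250, also near ZIPIC and Sry-beta, had a score at the 1.04th percentile of its list, with the nearest stage 15 boundary 17.5 kb away. Boundaries without a stage 15 partner within 10 kb also lay at term and slam, at the dorsoventral genes sna and dpp (35 kb), at the NSL gene MBD-R2 (40 kb), and at su(Hw), ash1, srp and grh. They lay at RpL10, RpS16, RpS30 and RpL7-like too, and 2.9 to 4.95 kb from nsl1, tsg, msl-2, up and abd-A. In the other direction, stage 15 boundaries without a stage 5 partner within 10 kb lay at Pc of the Polycomb group, the synaptic gene Syt1, the epidermal enzyme gene Ddc, the tracheal and neural regulator vvl, and RpLP0, RpS29 and RpS12. Of 56 ribosomal protein genes at a stage 15 boundary, 48 were at a stage 5 boundary (85.7%, 74.3 to 92.6). That count lay above the 32 to 45 of the central 95% of random sets, where 69.0% of all genes were kept, and inside the 36 to 48 of sets matched on score decile.

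**Figure D3:**
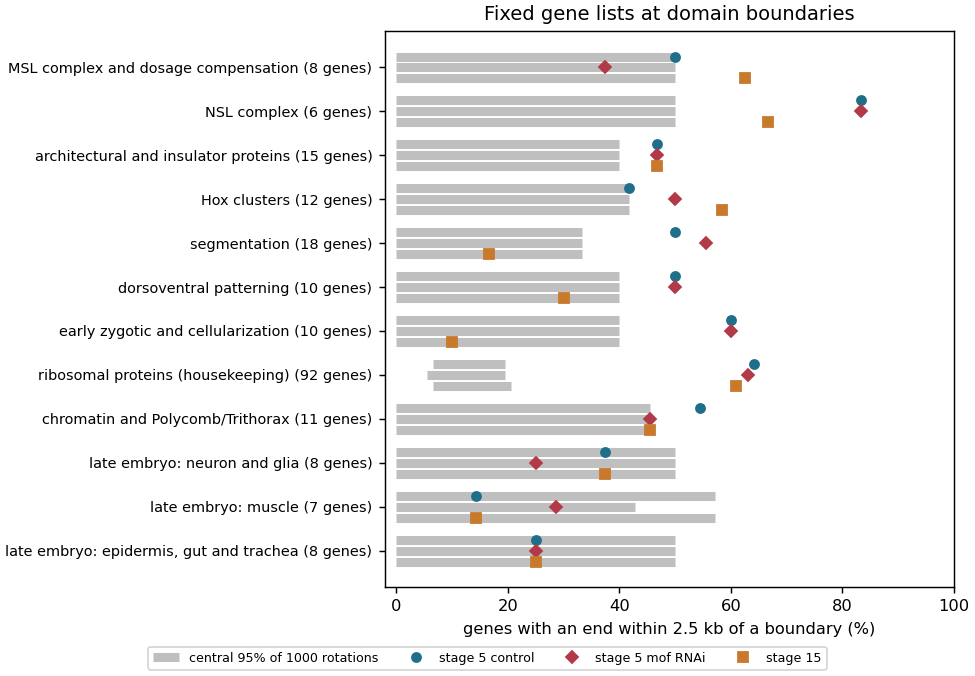
Percent of the genes of each fixed list with an annotated end within 2.5 kb of a boundary in the stage 5 control (circles), stage 5 mof RNAi (diamonds) and stage 15 (squares) lists; grey bars are the central 95% of 1000 rotations of each list. Segmentation genes stand at 50.0%, 55.6% and 16.7%, and ribosomal protein genes at 64.1%, 63.0% and 60.9%, where all protein-coding genes stand at 31.6%, 29.5% and 34.5%.

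Across the genome, 1598 of 2591 stage 5 control boundaries had a stage 15 partner (61.7%, 59.8 to 63.5, rotation mean 15.7%), and 1598 of 2785 stage 15 boundaries had a stage 5 partner (57.4%, 55.5 to 59.2). In all 3 lists were 1404 of the 2591 (54.2%, 52.3 to 56.1). Of 2586 control domains, 827 (32.0%, 30.2 to 33.8) had both ends and nothing between them at stage 15. The shares on X and autosomes were 59.4% and 62.2%, a difference inside the central 95% of rotations (32.2th percentile). Among stage 5 boundaries without a stage 15 partner within 10 kb, the 10 most negative scores lay nearest to x16, Sry-beta, Myo81F, CG15628, CG1943, Mi-2, His2Av, lilli, B52 and CG13398. Among stage 15 boundaries without a stage 5 partner they lay nearest to lt, CycE, Spf45, Vtld, serp, Gpb5, CG40228, CG12567, eIF4B and Marf1. Of these, 7 lay toward the end of 2L (from 22411251) or 3L (from 26881251), up to 200 kb from the nearest gene end, and the stage 15 decile with the most negative scores was matched at 60.2% (54.4 to 65.8).

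In the bithorax complex, the boundary at the end of Ubx (3R 16653751 to 16656250), those starting at 16798751 and 16918751, to the left of abd-A and Abd-B, and that starting at 16968751 inside Abd-B were in all 3 lists. The boundary to the right of abd-A, starting at 16833751, was in both stage 5 lists, and at stage 15 the next lay at 16868751. The stage 15 list had 1 boundary inside Abd-B where both stage 5 lists had 2. Inside Ubx the stage 15 list had 1 boundary, starting at 16701251, where the stage 5 lists had 2, starting at 16716251 and 16731251. Its boundary starting at 16733751, 0.574 kb past the gene, matched the second of these, 1 bin away. Antp held 3 boundaries in each stage 5 list and 1 at stage 15, when another lay 0.772 kb from a gene end. At stage 15, inv and en lay in 1 domain of 77.5 kb with no boundary inside inv. In both stage 5 lists a boundary lay 0.535 kb inside the left end of inv. It left en and the rest of inv together in 55 kb. At msl-3 a boundary lay in the gene at stage 15 and 9.47 kb away in both stage 5 lists.

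**Figure D4:**
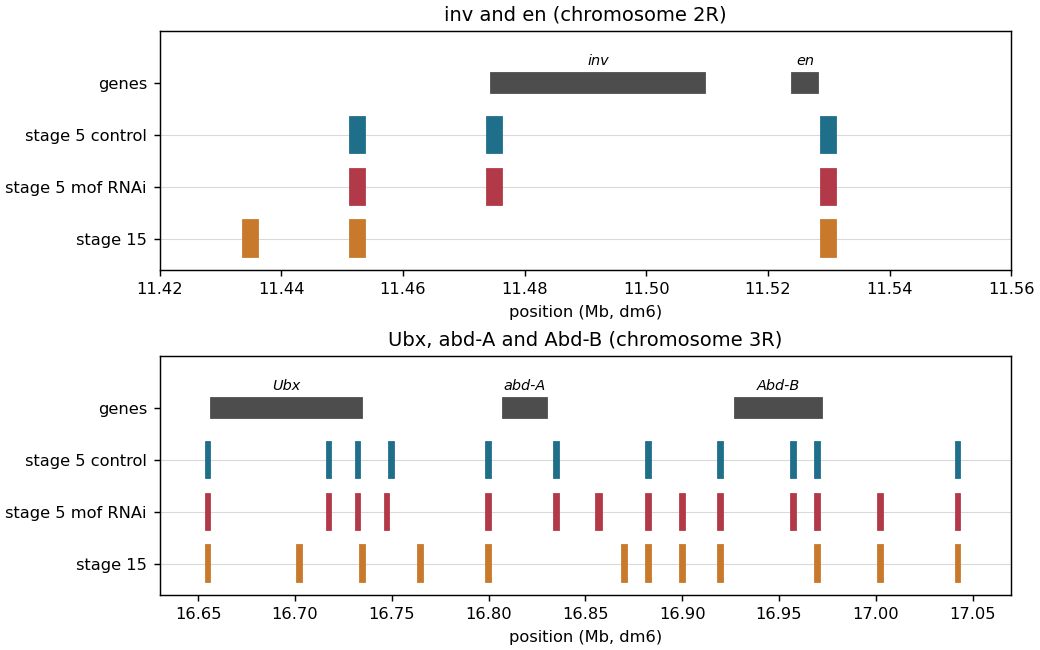
Boundaries (coloured boxes, drawn to scale) of the 3 lists and the annotated genes (grey) around inv and en on 2R and around Ubx, abd-A and Abd-B on 3R, by position in Mb of dm6. The boundary starting at 11473751 at inv is in both stage 5 lists and not at stage 15.

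The third comparison asked which stage 5 boundaries recurred at stage 15 by their status under mof RNAi. Of boundaries shared by both stage 5 lists, 68.9% (66.8 to 70.8, n = 2039) had a stage 15 partner. The share was 35.1% (31.3 to 39.2, n = 552) for control-only boundaries and 21.7% (18.2 to 25.7, n = 460) for those called after mof RNAi only, with rotation means of 15.2 to 15.8%. The control-only share exceeded the mof RNAi-only share by 13.4 percentage points (95% bootstrap interval 7.90 to 18.8). On X the shares were 67.0%, 35.1% and 16.2%. Control-only boundaries had less negative scores than shared ones (medians -0.0118 and -0.370 in the control list). Control boundaries had a stage 15 partner in 81.9% of the most negative score decile and 22.0% of the least. With the 50% of each stage 5 list with the most negative scores as query, 78.4% of shared and 60.6% of control-only boundaries had one. Shared and control-only boundaries were not weighted to the same score deciles, so their gap is not separated from score. Of the 10 genes of the fixed lists at a boundary in control and not after mof RNAi, 4 were at a stage 15 boundary (roX1, RpS3, RpL27 and RpL4) and 6 were not (msl-1, su(Hw), sna, brm, RpL10 and nSyb). Of the 9 genes at a boundary after mof RNAi and not in control, 6 were. These genes are not the boundary classes, since the boundaries at 2 of the 10 and 6 of the 9 had a partner within 2.5 kb in the other stage 5 list, outside the window around the gene's ends.

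Boundaries lay at the ends of genes. In control, 76.1% (74.4 to 77.7) had an end of a protein-coding gene within 2.5 kb, after mof RNAi 73.7% (71.9 to 75.4) and at stage 15 76.4% (74.8 to 77.9), against rotation means of at most 41.3%. Of 92 ribosomal protein genes, 59, 58 and 56 were at a boundary in the 3 lists, above all rotations, whose means were 12.3 to 13.4%. Of all 13842 protein-coding genes, 31.6%, 29.5% and 34.5% were at a boundary in the 3 lists, a share above the rotation means of every gene list. NSL genes stood at 5, 5 and 4 of 6, and architectural protein genes at 7 of 15 in each list, Cp190, BEAF-32, pita, mod(mdg4), vtd and SMC1 among them in all 3. Genes of the Hox clusters, a list that also holds bcd and ftz, stood at 5, 6 and 7 of 12. Dorsoventral genes stood at 5, 5 and 3 of 10, and Polycomb and Trithorax genes at 6, 5 and 5 of 11. The late embryo lists lay inside the central 95% of rotations at every stage, with 3, 2 and 3 of 8 for neuron and glia, 1, 2 and 1 of 7 for muscle, and 2 of 8 throughout for epidermis, gut and trachea.

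Boundaries at gene ends were called again more often. Of control boundaries with a gene end within 2.5 kb, 84.2% (82.5 to 85.8) had a partner after mof RNAi, and of the 620 others 61.1% (57.2 to 64.9). At stage 15 the shares were 71.8% (69.8 to 73.7) and 29.5% (26.1 to 33.2). Control-only boundaries had a gene end nearby in 56.3% (52.2 to 60.4), above all 1000 rotations. Boundaries called after mof RNAi only had 1 in 42.6% (38.2 to 47.2), at the 70.2th percentile of rotations.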

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

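The comparison weighted by domain length and the split of unmatched boundaries by decile were chosen only after the results they concern were seen. The numbers in the boundary names lie outside the positions and scores on which the planned comparisons rest. Between neighbouring boundaries, 4756 bins were left out of the stage 5 control map and 4737 of the stage 5 mof RNAi map. The stage 15 numbers showed 0 missing, which does not settle whether that map left out bins.

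Fewer stage 15 boundaries had a stage 5 control partner (57.4%) than mof RNAi boundaries did (81.6%). Left-out bins as the whole cause are argued against: in stage 5 domains without left-out bins the share was 72.0% (69.8 to 74.2, n = 1590), below the lower bound of 80.0% for mof RNAi boundaries. In domains with left-out bins it was 38.1% (35.4 to 40.9, n = 1189). With domains weighted to the same lengths the share was 10.7 points (6.18 to 15.3) higher without left-out bins, so these bins may account for part of the gap. Stage, the libraries pooled at stage 15, which are not stated, and the authors' calling at each stage stay open as untested explanations for the rest.

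Of stage 15 boundaries in the decile with the most negative scores without a stage 5 partner, 77.8% (69.1 to 84.6, n = 108) lay in stage 5 domains with left-out bins, beside 57.5% (50.8 to 64.0, n = 212) in deciles 2 to 4. Over all deciles the share was 62.3% (59.5 to 65.0, n = 1181). These shares were not weighted by domain length.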

How the results depend on the processing

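Restricting boundaries to domains without left-out bins, gene ends of every biotype, and every alternative for the kept segmentation and early zygotic genes were chosen only after the data were seen. Of all values recomputed under an alternative, 98 stayed within their interval or on the same side of their test, 71 moved, 6 became weaker and 0 reversed. Except where an alternative's construction shows it (a wider tolerance or window matches more, a shorter list has fewer boundaries), the cause was not tested. The X minus autosome difference ran from -0.962 to -5.79 points, at percentiles from 2.82 to 37.9 of the rotations. Against single autosomal arms, the X difference ran from -0.664 (3L) to -4.61 points (2R), at percentiles from 3.05 to 46.2.

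With tolerances of 0, 5 and 10 kb, control boundaries called after mof RNAi stood at 69.7%, 81.0% and 82.9%, and mof RNAi boundaries called in control at 72.3%, 84.0% and 85.9%. Stage 5 boundaries called at stage 15 stood at 48.7%, 67.1% and 73.1%, and stage 15 boundaries called at stage 5 at 45.3%, 62.4% and 68.0%. For the 50% of both lists with the most negative scores, the stage 5 shares were 84.5% and 87.6%. With only the query list so restricted, the 4 shares were 89.8%, 93.1%, 76.5% and 70.0%. Without left-out bins beside the boundary, the first 3 were 83.8%, 87.9% and 69.5%.

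Of shared boundaries, 58.4%, 73.6% and 78.3% recurred at stage 15 with tolerances of 0, 5 and 10 kb, 62.7% with the most negative 50% of all 3 lists, 78.4% with the most negative 50% as query, and 74.8% without left-out bins. Control-only boundaries stood at 26.5% and 47.7% with 0 and 10 kb, at 48.3% and 60.6% with the most negative 50%, and at 41.8% without left-out bins. Boundaries called after mof RNAi only stood at 16.3%, 26.8% and 37.1% with the 3 tolerances and at 31.4% with the most negative 50% as query. Rotations at these tolerances were not run by class. For all control boundaries against stage 15, their means were 5.08%, 26.2% and 44.9% at 0, 5 and 10 kb. The mof RNAi-only shares at 5 and 10 kb and the control-only share at 10 kb are therefore not read as recurrence. The 50% of each list with the most negative scores held 1296, 1250 and 1393 boundaries, with median domains of 52.5, 57.5 and 55 kb. At 10 kb the unmatched minus matched median scores were 0.383 (mof RNAi against control), 0.373 (control against stage 15) and 0.133 (stage 15 against control).

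Within 5 kb of a gene end lay 81.6%, 80.3% and 81.6% of boundaries in control, mof RNAi and stage 15, within 1 kb 58.0%, 56.4% and 61.6%, and with ends of every biotype 78.8%, 76.6% and 79.0%. With 1 kb windows, genes of the Hox clusters stood at 8.33% in both stage 5 lists, segmentation genes at 16.7% and 11.1%, and epidermis, gut and trachea genes at 0% in both. Ribosomal protein genes stood at 52.2% in control and 48.9% at stage 15, dorsoventral genes at 20% after mof RNAi and 10% at stage 15, and muscle genes at 0% at stage 15. With 5 kb windows, Polycomb and Trithorax genes stood at 81.8%, 72.7% and 81.8%, muscle genes at 57.1% in control, and MSL genes at 75% and ribosomal protein genes at 72.8% after mof RNAi.

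Segmentation genes at stage 15 boundaries became 33.3% with 1 kb windows. Early zygotic genes became 42.9% with 5 kb windows, 25% with 1 kb windows, 50% with stage 15 boundaries within 10 kb, and 33.3% without left-out bins. Both lists together became 28.6% with 1 kb windows. In these 6 cases the count no longer lay outside the central 95% of random sets.

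Leaving out chromosome 4 or keeping every sequence changed nothing, since the lists hold 5 arms. Motif windows and every transcript start were not run, for lack of a genome sequence and of transcripts, and leaving out replicates was not run, for lack of lists per replicate. No paired analysis was possible because the pooled lists carry no replicate numbers. Depth is unknown, so the share of unmatched boundaries owed to it was not estimated.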

Other observations

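The gene list comparisons, the weighted X difference, the score-matched gene sets, the gene sets without left-out bins and the ratio of left-out bins were chosen only after the results they concern were seen. Among genes of the fixed lists, 10 were at a boundary in control and not after mof RNAi, and 9 after mof RNAi and not in control. Of the 10, roX1, RpS3, RpL27 and RpL4 were at a stage 15 boundary (40.0%, 16.8 to 68.7), and msl-1, su(Hw), sna, brm, RpL10 and the synaptic gene nSyb were not. The boundaries at roX1 and RpL4 had a partner 1 bin away after mof RNAi, beyond the window around the gene's ends. Of the 9, 6 were at a stage 15 boundary (66.7%, 35.4 to 87.9): roX2, the GAGA factor gene Trl, the Hox gene lab, the pair-rule gene opa, RpL9 and RpS24. RpL7A, tsg and up were not. All 9 of these boundaries had a control partner within 10 kb, where the rotation mean for mof RNAi boundaries was 41.9%. Those at tsg, up, RpS24, Trl, opa and lab had a partner within 2.5 kb, so for these 6 genes the status rests on a difference of 1 bin. Whether such a partner is the same boundary shifted was not tested.

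Of 102 genes at a boundary in both stage 5 lists, 75 were at one at stage 15 (73.5%, 64.2 to 81.1). Of 82 genes at a boundary in neither, 12 were (14.6%, 8.57 to 23.9), and these include msl-3, Antp, Pc, Syt1, Ddc and vvl. At Sxl a boundary lay 0.553 kb from a gene end in all 3 lists, while the boundaries on either side of the gene lay 70 kb apart in control, 114 kb after mof RNAi and 148 kb at stage 15, a stretch of 2 domains in each. The boundary to the left of mof lay 53.5 kb from the gene in control and 109 kb after mof RNAi. With each score decile weighted equally, the X minus autosome difference in control boundaries called after mof RNAi was -4.11 points (bootstrap interval -8.34 to -0.230), an interval that treats neighbouring boundaries as independent, as the rotations do not.

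Of 9 segmentation genes at stage 5 boundaries 2 (en and hh) were at stage 15 boundaries, and of 6 early zygotic genes 1 (Sxl), the lists that stood apart among 11 of protein-coding genes. The scores of these boundaries as the whole cause are argued against, since 0.65% and 0.2% of 2000 random gene sets matched on score decile kept as few. Left-out bins as the whole cause are argued against for segmentation genes, where 2 of 8 genes without such bins were kept and 0.27% of random sets kept as few. For early zygotic genes this stays open, with 1 of 3 kept and 13.7% of random sets. Genes without a left-out bin were 8 of the 9 segmentation genes but only 3 of the 6 early zygotic genes. With both lists together, a left-out bin lay beside 26.7% (10.9 to 52.0) of the 15 genes, and 45.1% of all genes at stage 5 boundaries. The embryos' stage, the authors' calling at each stage and the pooled libraries stay open as untested explanations, and expression values were not used here.

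Control-only boundaries recurred at stage 15 in 35.1% and mof RNAi-only boundaries in 21.7%. A lower rank of the latter within their own list as the whole cause is argued against, since the difference weighted to the same score deciles was 11.9 points (6.70 to 17.3). So are left-out bins, since without them it was 17.7 points (8.05 to 27.6), from 41.8% of 196 and 24.1% of 137. The maps left out nearly the same share of bins (ratio 0.999), but the authors' bin filter is not given in the sources used here, so a lower depth of the 2 mof RNAi libraries cannot be told apart from the depletion of mof. The libraries pooled at stage 15, which are not stated, stay open too. More control-only boundaries (56.3%) than mof RNAi-only ones (42.6%) had a gene end nearby. Control boundaries with a gene end nearby recurred at stage 15 in 71.8%, and others in 29.5%. This was not tested as a cause.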
